A study of Mus musculus with 4 samples.

How the data were processed

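The files cover 4 droplet libraries of mouse LSK cells, WT and Mettl3 cKO, each with the empty GFP vector and with the SON virus, 1 library per combination. Per the labels' protocols, sorted LSK cells were kept in medium with SCF (50 ng/ml), IL-3, IL-6 and TPO (10 ng/ml each) and Flt3 ligand (20 ng/ml), infected, and sorted for GFP 48 h later. The same labels give 5000 target cells, viability above 80%, doublets below 5%, and the 3' v2 protocol of 10x Genomics. The deposited files list more barcodes than the set of that protocol holds, so the chemistry is in doubt and could not be settled. They do not give the Cre line, the deleted part of Mettl3, the number of mice or the SON construct.

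Each deposited matrix holds raw UMI counts in genes and barcodes, which the authors made with Cell Ranger 7.1.0 on the mm10 genome, per the submitters' processing notes. The header of each matrix names Cell Ranger 4 instead, and this difference could not be settled. No cell calling had been applied: 1501350, 1618041, 1346188 and 1608461 barcodes were listed (libraries here and below in the order WT empty vector, WT SON, cKO empty vector, cKO SON), with 101380799, 95993622, 100051761 and 99424322 UMIs. The gene annotation release was not given in the sources used here. Coordinates are those of GENCODE vM21 on GRCm38 (mm10), matched by Ensembl ID, and all 7646 compared genes had a match.

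Barcodes counted as cells from 10% of the 99th percentile of UMIs among the 5000 largest barcodes of the library, which gave thresholds of 4293, 3925, 3490 and 4127 UMIs and 4556, 4837, 6659 and 5262 barcodes. Barcodes under 500 genes (0 in each library) or over 10% mitochondrial UMIs (279, 283, 116 and 174) were left out. Doublets were scored with Scrublet at an expected rate of 5%. Its automatic threshold marked 0.0935%, 0%, 0.0306% and 0% of cells, below the 0.5% at which the caller counted as working, so the 5% of cells with the highest scores were left out (188, 212, 294 and 248 after ties). The kept cells held 78.6%, 72.6%, 72.7% and 62.7% of all UMIs. Mitochondrial and ribosomal protein genes made up 34.2%, 35.6%, 37.1% and 38.8% of the UMIs in cells.

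The kept cells of all libraries were clustered together without integration, since library and group are the same thing here. Counts were scaled to 10000 per cell, logged, and reduced to 2000 variable genes (cell cycle, histone, ribosomal protein, mitochondrial and sex-linked genes barred) and 30 principal components, followed by a graph of 15 neighbours and Leiden clustering at resolution 0.6, seed 1. A cluster was named by the marker list with the highest mean z-score when that score was above 0.3, at least 3 of its markers were raised 1.5-fold, and no other list had more markers among the 10 leading genes. Clusters that failed the rule stayed unnamed. Markers and rule were fixed before the counts were read. Cell cycle phases were scored with scanpy on cells thinned to 4000 UMIs, which left out 130 cells of the cKO library with the empty vector.

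For gene comparisons the UMIs of all kept cells of a library were summed and divided by their total. Genes with a mean CPM of at least 10 over the 4 libraries were compared. Genes at least 1.5-fold apart (2-fold for the ratio of ratios) were counted by size, not tested, since a single library per group has no variance between replicates and cells or genes are no replacement for replicates. Ratios carry exact conditional binomial intervals, single levels exact Poisson intervals, shares of cells exact binomial intervals, and ratios of ratios intervals from 20000 Poisson resamples (a resampled 0 set to 0.5), all at 95%. A count of 0 was set to 3 for a bound. The comparisons were cKO over WT with the empty vector, SON over empty vector in WT and in cKO, cKO with SON over WT with the empty vector, and the ratio of the 2 SON ratios. Return toward WT was counted among genes past 1.5-fold in cKO, against the product of the 2 gene counts over all genes, a simulation with 100 draws in which SON had no effect, and a random split of the shared library.

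There were 20 gene lists fixed before the data were examined: ISGs, double-stranded RNA sensing, MHC class I, inflammatory and NF-kB, HSC quiescence, MYC targets, S phase, G2M, p53 targets, integrated stress and unfolded protein response, immediate-early and heat shock, splicing and nuclear speckle, ribosomal proteins, mitochondrially encoded, respiratory chain, glycolysis, cholesterol synthesis, histones, m6A machinery and sex-linked genes. Beside them stood 14 marker lists of cell types. Some of these lists, and Myc and Ccl5 as genes to report, were chosen from earlier knowledge of Mettl3 and SON in blood cells. A list median needed 3 measured members, and its percentile came from 10000 random lists drawn in 20 bins of mean expression. Lists overlap in part, for example 3 genes shared by G2M and p53 targets.

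Genes named in the report follow a fixed rule: the 12 highest and 12 lowest genes past 1.5-fold in each comparison (8 and 8 past 2-fold for the ratio of ratios), Son, Mettl3, Myc and Ccl5 always, and up to 2 of the highest and 2 of the lowest members of each list. Mitochondrial, ribosomal protein, sex-linked, predicted and clone-named genes and immunoglobulin or T cell receptor segments were not ranked. Intronic and exonic tags were not told apart, and tags of paralogs or pseudogenes can be lost or shared.

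Other settings fixed beforehand were TMM factors from edgeR, median-of-ratios factors, and totals without mitochondrial and ribosomal protein genes; a minimum CPM of 5, 50 or none; a 2-fold size; cell thresholds of 5% and 20% of the percentile or 1000 UMIs; mitochondrial limits of 5% and 20%; doublet calls kept; equal weight per cell; cells thinned; free RNA of barcodes with 1 to 50 UMIs subtracted; means of within-class ratios over classes of at least 100 cells in both libraries; and clustering at resolutions 0.3 and 1.0 or with 4000 variable genes. The 4 alternatives added after the data were seen are named in the closing section. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, python-igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.

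The scripts were tested on simulated counts with 200 genes set apart in each comparison. Genes set 2-fold or 4-fold apart were all found, those at 1.5-fold in 50%, 48%, 52% and 40% of cases (cKO over WT, SON in WT, SON in cKO, cKO with SON over WT), and 0 unchanged genes passed. The intervals held the true ratio in 95.5%, 94.5%, 95.5% and 93.5% of cases. Random lists fell outside percentiles 5 to 95 in 8.5%, 13%, 9.5% and 10% of draws.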

Results

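LSK cells, the lineage-negative, Kit- and Sca-1-positive bone marrow fraction that holds mouse haematopoietic stem cells (HSC) and multipotent progenitors (MPP), were read by single-cell RNA sequencing of transcript 3' ends. The cells came from wild-type (WT) mice or mice with a conditional knockout (cKO) of Mettl3, the catalytic subunit of the enzyme that writes N6-methyladenosine (m6A) on RNA. They had received a lentivirus for SON, a nuclear speckle protein needed for pre-mRNA splicing, or an empty GFP vector, and GFP-positive cells were sorted after 48 h. Each of the 4 combinations was 1 library, so there is no replicate check, no test was run, and every difference below could also be a difference between 2 preparations. Intervals in parentheses are 95% intervals for counting error only. Ratios compare the summed counts of all kept cells, scaled by the library total (CPM), and list medians are log2 ratios given with their percentile among 10000 random lists of the same mean expression.

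The 4 libraries held 4089 (WT, empty vector), 4342 (WT, SON), 6249 (cKO, empty vector) and 4840 (cKO, SON) kept cells, with 79693120, 69657091, 72708975 and 62367091 UMIs. Median UMIs per cell were 18938, 15168, 9848 and 11246, and median genes per cell were 4024, 3668, 2867 and 3057.5. A UMI in a kept cell was seen for 22013 genes, and 7646 had a mean CPM of at least 10. Comparisons of genes are over these 7646, and a member of a gene list counts as higher or lower from a difference of 25% (ratio 5/4 or 4/5).

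Son (ENSMUSG00000022961, chromosome 16, 91647506 to 91679221) was close to equal with and without the SON virus, at 437 CPM (432 to 442) in WT with the empty vector, 447 (442 to 452) in WT with SON, 509 (504 to 514) in cKO with the empty vector and 499 (494 to 505) in cKO with SON. The SON over empty ratio of Son was 1.02 (1.01 to 1.04) in WT, log2 0.033, which became -0.018 with TMM scaling and -0.049 with median-of-ratios scaling. In cKO the ratio was 0.981 (0.966 to 0.996), log2 -0.028, which became 0.011 when mitochondrial and ribosomal protein genes were left out of the total. Within the cKO clusters 0, 2, 3 and 4 Son was slightly lower with SON, at 0.922, 0.913, 0.868 and 0.947. A 3' tag of a vector transcript need not map to the Son 3' end, so these counts check nothing about the virus. Son was higher in cKO than in WT with the empty vector, at a ratio of 1.16 (1.15 to 1.18). Mettl3 (ENSMUSG00000022160, chromosome 14, 52294841 to 52305128) was at 15.6 CPM (14.7 to 16.4) and 16.4 (15.4 to 17.4) in the WT libraries and at 6.30 (5.74 to 6.90) and 6.13 (5.53 to 6.77) in the cKO libraries, empty vector before SON. Its cKO over WT ratio was 0.405 (0.363 to 0.451), and its SON over empty ratio was 1.05 (0.971 to 1.14) in WT and 0.972 (0.847 to 1.12) in cKO. Pooled over the same cKO clusters, Mettl3 was at 4.82 CPM (4.22 to 5.47) with the empty vector and 5.90 (5.30 to 6.55) with SON. Those intervals overlap slightly. The deleted part of Mettl3 is not given in the labels, and tags outside it do not measure the deletion. Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374), a growth-promoting transcription factor, had a cKO over WT ratio of 0.812 (0.782 to 0.843) with the empty vector. With SON over empty, Myc was at 1.08 (1.04 to 1.12) in WT and 1.03 (0.986 to 1.07) in cKO over all cells. Pooled over the cKO clusters 0, 2, 3 and 4, however, Myc was higher with SON. It was at 57.2 CPM (55.1 to 59.3) with the empty vector and 68.6 (66.6 to 70.8) with SON there.

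**Figure D1:**
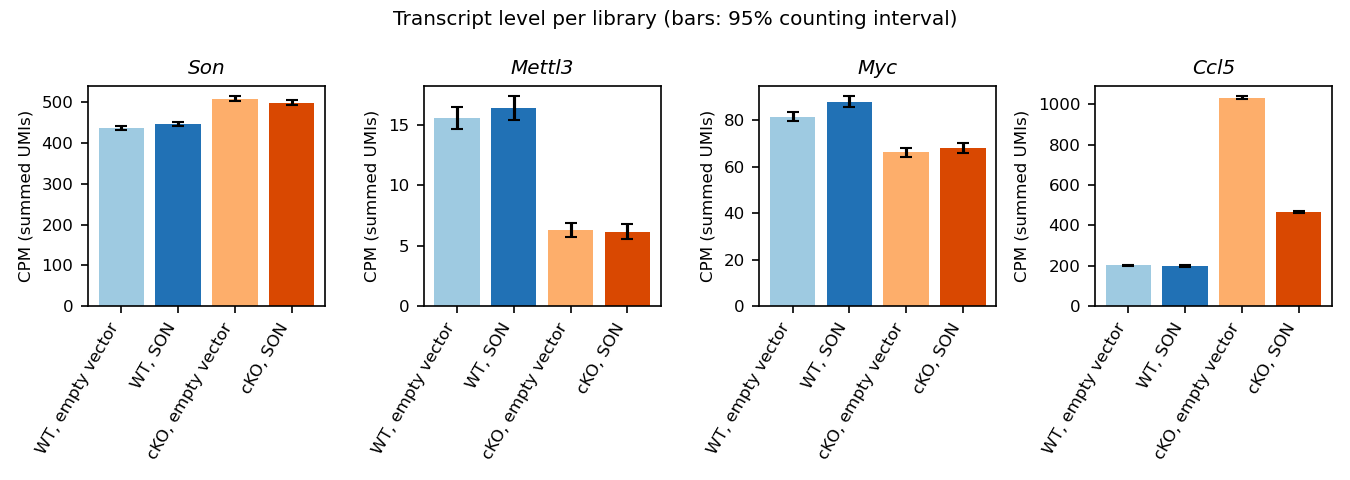
CPM of Son, Mettl3, Myc and Ccl5 in the 4 libraries (WT and cKO, empty vector and SON), with 95% counting intervals as bars. Ccl5 was higher in both cKO libraries, and lower with SON than with the empty vector among them.

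HSC/MPP-like cells were 19.1% (17.9 to 20.3) of the cells of WT with the empty vector and 47.7% (46.2 to 49.1) of WT with SON. Nearly all of these were in cluster 1, where the markers Hlf, Ifitm1, Cd34 and Msi2 were raised. In cKO they were 43.4% (42.2 to 44.6) with the empty vector and 52.6% (51.2 to 54.0) with SON, nearly all in clusters 0 and 3. Mecom, Mllt3, Procr, Meis1 and Ly6a were raised in both of these clusters, and Hlf also in cluster 3, so the naming markers differ between genotypes. Interferon genes such as Rtp4, Ifit1 and Ifit3 are among the leading genes of clusters 0 or 3, and Gbp4 and Ifi44 among those of cluster 1, so the sizes of these clusters are not comparable between genotypes. Granulocyte-monocyte progenitor-like cells were 19.3% of WT with the empty vector, 7.19% of WT with SON, 8.32% of cKO with the empty vector and 0.413% of cKO with SON. In the same order, lymphoid-primed-like cells were 19.5%, 10.3%, 2.99% and 0.124%, and megakaryocyte-like cells (cluster 5) were 14.7%, 21.0%, 3.34% and 1.18%. Cluster 5 is mixed, with the erythroid genes Hbb-bs, Car1 and Gata1 also among its leading genes. Monocyte-like cells (cluster 9, mixed too, with the macrophage genes Gpnmb, Msr1 and Trem2 among its leading genes) were 8.24%, 1.91%, 0.864% and 0.0413%, mature neutrophil-like cells 4.65%, 0.507%, 0.848% and 0 of 4840 cells, which allows a share of up to 0.0762%. Mast cell/basophil-like cells were 3.28%, 1.80%, 0.576% and 0.103%, and B cell-like cells were 0.660%, 0.0230%, 0.528% and 0 of 4840. Dendritic-like cells were 0.171%, 0 of 4342 (up to 0.0849%), 0.272% and 0 of 4840. Unnamed cells (clusters 2, 4, 8 and 14) were 10.4%, 9.58%, 38.9% and 45.5%, and nearly all of clusters 2 and 4 was cKO. Cluster 2 is led by Cd48 and Ccl9, with Serpina3g further down its leading genes. Cluster 4 is led by Serpinb2, C1qc (a macrophage gene), Clu and Nrgn. Further down its leading genes are Gp5, Itgb3 and Selp, genes of platelets and megakaryocytes. The best list of cluster 4 (1120 and 910 cKO cells) was that of megakaryocytes, with 7 markers raised, so the small megakaryocyte-like share in cKO rests on the naming rule. For cluster 8 (421 and 411 WT cells, empty vector before SON) the best list was that of granulocyte-monocyte progenitors, with all its markers raised. Its leading genes Prg2 and Epx, markers of eosinophils, left it unnamed, so the granulocyte-monocyte progenitor-like shares in WT rest on the naming rule too. Shares follow the LSK sort, the culture, the GFP gate and the depth gap between libraries as well as the cells present.

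**Figure D2:**
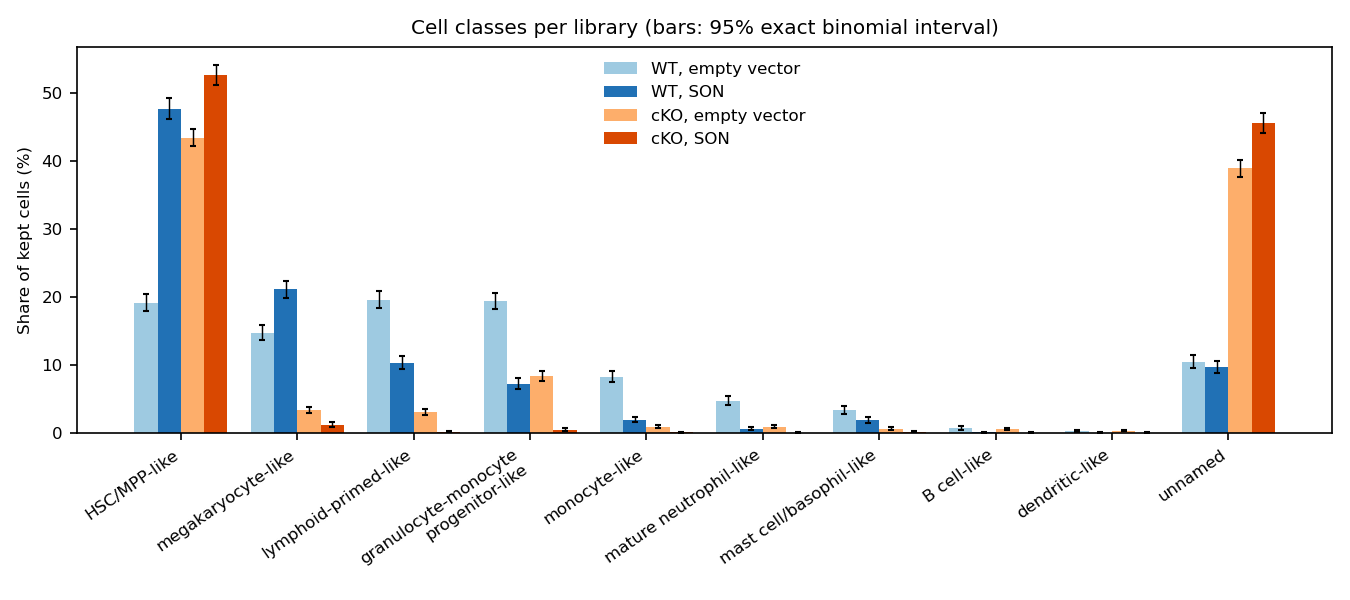
Share of kept cells (percent) in each named class for the 4 libraries. HSC/MPP-like cells are cluster 1 in WT and clusters 0 and 3 in cKO, and the myeloid classes were smallest in cKO with SON.

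Clusters 0, 2, 3 and 4 had at least 95% of their cells from the cKO libraries and are called cKO-dominated here. They held 80.7% of the cKO cells with the empty vector and 98.0% of those with SON. The 1206 other cells with the empty vector (19.3%, 18.3 to 20.3) lay in the clusters of the WT cells, as did 96 with SON (1.98%, 1.61 to 2.42). In cKO with the empty vector, Mettl3 was at 4.82 CPM inside the cKO-dominated clusters and 9.36 outside, Ccl5 at 1491 and 80.2, Son at 551 and 423, and Myc at 57.2 and 85.3.

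Cells called as S or G2M phase, after thinning to 4000 UMIs per cell, were 92.0% of WT with the empty vector, 87.8% of WT with SON, 76.2% of cKO with the empty vector and 73.7% of cKO with SON. Without thinning they were 92.2%, 88.5%, 74.7% and 72.7%. In HSC/MPP-like cells the thinned shares were 91.0% and 79.0% in WT (cluster 1) and 68.7% and 68.9% in cKO (clusters 0 and 3). Phase calls rest on few genes per cell, free RNA from lysed cells can raise them, and cycling is not read from them alone.

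With the empty vector, interferon-stimulated genes (ISGs), the antiviral effectors switched on by type I interferon, were higher in cKO than in WT, as was the chemokine Ccl5. Genes of stem cells and of MHC class I antigen display were also mostly higher. Neutrophil and monocyte genes, Flt3 (the cytokine receptor of early lymphoid and dendritic progenitors), and the enzymes of cholesterol synthesis and glycolysis were lower. Among ISGs, Rtp4 was at a ratio of 13.6 (12.7 to 14.6), Iigp1 at 11.2, Ifit1 at 10.5 (9.78 to 11.2) and Isg15 at 10.4, and Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) was at 1031 against 201 CPM, a ratio of 5.12 (5.03 to 5.21). Flt3 (ENSMUSG00000042817, chromosome 5, 147330741 to 147400489) was at 0.103 (0.0883 to 0.120).

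At least 1.5-fold higher in cKO were 842 genes and lower were 501, or 62.7% higher. The split was 751 and 633 (54.3%) with TMM scaling, 703 and 714 (49.6%) with median-of-ratios scaling, and 991 and 364 (73.1%) without mitochondrial and ribosomal protein genes in the total. Gprc5b (ENSMUSG00000008734, chromosome 7, 118972047 to 118995211), an orphan G protein-coupled receptor of stem cells, was highest at 32.9 (26.1 to 41.9). It was followed by the zinc finger gene Zfp467 at 23.4 (18.9 to 29.4), the imprinted growth regulator Phlda2 at 17.5 (14.5 to 21.3), the protease inhibitor Serpina3f at 13.3 and the cytokine Ltb (lymphotoxin beta) at 12.9. The G protein subunit Gng11 was at 10.2, the lipid carrier Apoe at 10.1, and Pdzk1ip1, a gene of long-term HSC, at 9.86. The lowest after Flt3 were Lpl at 0.163, Tgfbi at 0.171, F10 at 0.191, Egln3 at 0.193, Ahnak at 0.216, Mcemp1 at 0.219 and the lactate exporter Slc16a3 at 0.221. C3 was at 0.222, Chil3 at 0.223, Cybb (a subunit of the phagocyte oxidase) at 0.240 and Lgals3 at 0.254.

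Of 39 ISGs, 36 were higher in cKO and 0 lower, with 3 between (median 1.22, percentile 100). Double-stranded RNA sensing genes, 7 of 11 shared with the ISG list, had 9 higher and 2 between (0.75, percentile 100), with Zbp1 at 5.12 and Oas3 at 3.28. Of 16 MHC class I genes, 11 were higher and 5 between (0.68, percentile 100), from H2-Q7 at 5.13, whose reads can be shared with its paralogs, to Psmb10 at 0.843. Inflammatory and NF-kB genes had 9 of 15 higher and 6 between (0.38, percentile 99.8), among them Ccl9 at 2.93. HSC quiescence and self-renewal genes had 14 of 17 higher, 1 lower and 2 between (0.89, percentile 100), with Mecom at 4.88 but Hlf at 0.605. The 10 measured HSC/MPP markers, 6 of them in the list just named, had 6 higher, 1 lower and 3 between (0.74, percentile 100). Among these markers Ly6a, also an interferon target, was at 6.91. Histone transcripts had 24 of 35 higher, 2 lower and 9 between (0.53, percentile 100), such as H1f0 at 2.53, and many of these genes share reads. p53 targets, genes of the DNA damage response, had 7 of 19 higher, 1 lower and 11 between (0.19, percentile 95.8), with Phlda3 at 1.97 and Zmat3 at 1.78 against Ccng1 at 0.752. In the m6A machinery, 4 of 15 were higher, 3 lower and 8 between (0.16, percentile 93.8), with Rbm15 at 1.98 and Ythdf2 at 1.75 beside Mettl3 itself.

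On the lower side, cholesterol synthesis had 20 of 22 genes lower and 2 between (-0.77, percentile 0), with Hmgcs1 at 0.387 and Lss at 0.429. Glycolysis had 13 of 17 lower, 2 higher and 2 between (-0.72, percentile 0), with Slc2a1 at 0.476 and Ldha at 0.492. MYC targets, mostly genes of ribosome making and growth, had 21 of 39 lower, 1 higher and 17 between (-0.36, percentile 0), such as Noc4l at 0.589. The integrated stress and unfolded protein response had 14 of 26 lower and 12 between (-0.36, percentile 0.01), with Asns at 0.516 and Hsp90b1 at 0.546. S phase genes had 21 of 42 lower, 1 higher and 20 between (-0.31, percentile 0.03), with Nasp at 0.581 but Fen1 at 1.59. G2M genes had 15 of 52 lower, 2 higher and 35 between (-0.15, percentile 20.9), with Bub1 at 0.583. Splicing and nuclear speckle genes had 18 of 42 lower, 1 higher and 23 between (-0.27, percentile 0.85), with Malat1, a speckle RNA, higher at 1.42. Nuclear respiratory chain genes had 8 of 28 lower and 20 between (-0.24, percentile 2.17), with Cycs at 0.656. Ribosomal proteins had 10 of 81 higher and 71 between (0.095, percentile 100). Mitochondrially encoded genes had 1 of 13 higher and 12 between (0.074, percentile 94.96, but -6.42e-05 with median-of-ratios scaling). Immediate-early and heat shock genes had 3 of 12 higher, 3 lower and 6 between (-0.033, percentile 58.0, but 0.032 without mitochondrial and ribosomal protein genes in the total), with Jund at 1.53. Of 3 measured sex-linked genes, 1 was lower and 2 between.

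Markers of mature and committed cells were lower beside the smaller myeloid, lymphoid and mast cell classes. All 8 granulocyte-monocyte progenitor markers were lower (-0.83, percentile 0; Cebpe at 0.397, Igsf6 at 0.444), as were all 5 neutrophil markers (-1.63, percentile 0; S100a8 at 0.359, S100a9 at 0.328). Monocyte markers had 4 of 5 lower and 1 higher (-1.71, percentile 0), with Lyz2 at 0.265. Lymphoid-primed markers had 2 of 3 lower and 1 higher (-1.75, percentile 0.03), and mast cell/basophil markers 3 of 4 lower and 1 higher (-1.76, percentile 0), with Cpa3 at 0.305 and Gzmb at 0.264. Dendritic markers had 2 of 6 lower, 1 higher and 3 between (-0.13, percentile 38.0). Erythroid markers had 3 of 4 higher and 1 lower (0.89, percentile 99.9, but -0.39 without a minimum CPM), with Blvrb at 2.92 and Tfrc, the transferrin receptor, at 0.489. Megakaryocyte markers had 2 of 5 higher, 1 lower and 2 between (0.14, percentile 85.9), with Itga2b at 2.05 and Pf4 at 0.784. Macrophage (2 measured), eosinophil (0), B cell (1), T/NK cell (1) and stromal or endothelial (0) markers were too few for a median in any comparison.

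Only 3 clusters (5, 6 and 7) had at least 100 cells in both libraries, and they held 14.7% of the cKO cells and 53.5% of the WT cells. Within them ISGs stayed higher (medians 0.19, 0.41 and 0.32), but Ccl5 was lower in cKO in clusters 5 and 7, at 0.278 and 0.522, with no clear difference in cluster 6, at 0.925 (0.840 to 1.02). Within the HSC/MPP-like class, in separate clusters by genotype, Ccl5 was higher at 3.44 (3.37 to 3.51). In the 3 clusters the medians of HSC quiescence genes (-0.041), inflammatory genes (-0.14), p53 targets (-0.21), the m6A machinery (-0.067), MYC targets (0.019), the stress response (0.0059) and respiratory chain (0.032) turned direction.

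**Figure D3:**
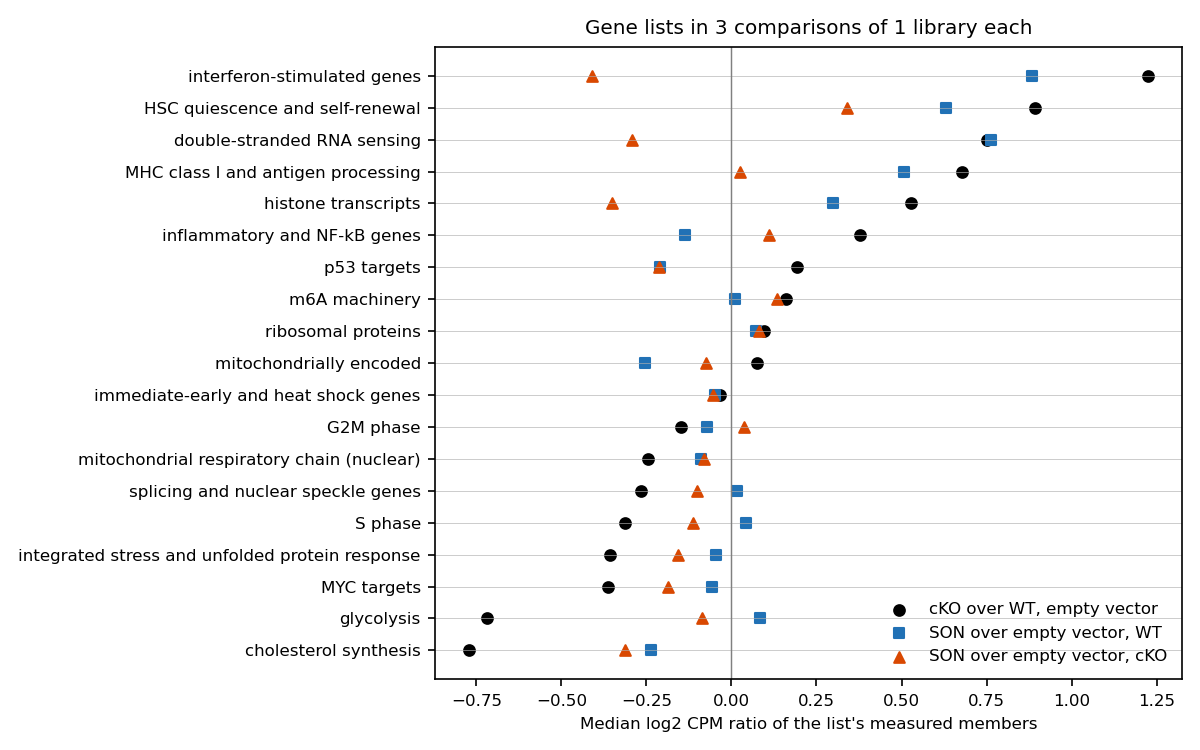
Median log2 CPM ratio of 19 gene lists in 3 comparisons: cKO over WT with the empty vector, SON over empty in WT, and SON over empty in cKO. ISG and double-stranded RNA sensing medians were above 0 in the first 2 and below 0 in the last.

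In WT cells with SON, ISGs and stem-cell genes were higher than with the empty vector, and neutrophil granule genes, which store antimicrobial proteins, were much lower. Ifi44, a gene induced by interferon (ENSMUSG00000028037, chromosome 3, 151730922 to 151749960), was at a ratio of 6.47 (5.66 to 7.41), and the interferon-inducible GTPase Iigp1 at 6.30 (5.52 to 7.21). Camp, the cathelicidin of neutrophil granules (ENSMUSG00000038357, chromosome 9, 109847379 to 109849617), was at 0.106 (0.0974 to 0.114). Ccl5 was almost equal over all cells, at 0.988 (0.966 to 1.01), yet lower within HSC/MPP-like cells at 0.552 (0.652 in cluster 1 alone) and within megakaryocyte-like cells at 0.400. The all-cell value rests partly on the few WT cells in cKO-dominated clusters (16 with the empty vector, 12 with SON). Without them Ccl5 was at 180 CPM (177 to 183) with the empty vector and 196 (193 to 199) with SON.

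At least 1.5-fold higher with SON were 261 genes and lower were 144 (64.4% higher), or 222 and 161 (58.0%) with TMM scaling, 204 and 184 (52.6%) with median-of-ratios scaling and 281 and 139 (66.9%) without mitochondrial and ribosomal protein genes in the total. More ISGs followed, with Rtp4 at 4.32 (4.01 to 4.66), Usp18, a brake on interferon signalling, at 4.05, Ifit3 at 3.86, Oasl2 at 3.70 and Ifit1 at 3.19. Stem-cell genes among the highest were Ly6a (Sca-1) at 3.76, Gprc5b at 3.43 and Pdzk1ip1 at 3.16, next to the keratin Krt18 at 3.39 and the metallothionein Mt2 at 3.36. Beside Camp, the lowest were Ngp at 0.119, Chil3 at 0.123, Lcn2 at 0.136, S100a9 at 0.170, Lyz2 at 0.177, Mcemp1 at 0.179 and Cybb at 0.180. Wfdc21 was at 0.191, S100a8 at 0.226, F10 at 0.240 and the signalling adaptor Tyrobp at 0.245.

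ISGs had 37 of 39 higher and 2 between (0.88, percentile 100), with the interferon regulator Irf7 at 2.82, and double-stranded RNA sensing 8 of 11 higher and 3 between (0.76, percentile 100), with Oas3 at 3.02. MHC class I had 11 of 16 higher and 5 between (0.51, percentile 100), with H2-Q6, which shares reads with paralogs, at 2.30. HSC quiescence genes had 13 of 17 higher and 4 between (0.63, percentile 100), with Mecom at 3.05, and HSC/MPP markers 9 of 10 higher and 1 between (0.77, percentile 100). Histone transcripts had 16 of 35 higher and 19 between (0.30, percentile 100), with Hist1h2ae at 1.82. Cholesterol synthesis had 6 of 22 lower and 16 between (-0.24, percentile 0), with Fdps and Mvd both at 0.678. p53 targets had 5 of 19 lower, 1 higher and 13 between (-0.21, percentile 0.01), with Zmat3 at 0.565 and Ccng1 at 0.580. Inflammatory genes had 4 of 15 lower, 1 higher and 10 between (-0.14, percentile 0.08), with Ccl9 at 0.669 and Irf1, an interferon regulator, at 1.46. Mitochondrially encoded genes had 4 of 13 lower and 9 between (-0.26, percentile 0). Glycolysis had 5 of 17 higher and 12 between (0.084, percentile 96.2), with Slc2a3 at 2.06 and Ldhb at 1.67.

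MYC targets had all 39 between (-0.056, percentile 5.14), and respiratory chain genes all 28 between (-0.088, percentile 0.785). G2M genes had 1 higher, 1 lower and 50 between (-0.073, percentile 0.16). The stress response had 2 of 26 higher, 3 lower and 21 between (-0.045, percentile 6.31), with Trib3 at 1.82 and Cebpb at 0.616. Immediate-early genes had 1 of 12 higher, 1 lower and 10 between (-0.049, percentile 9.51), with Egr1 at 2.63. The m6A machinery had all 15 between (0.011, percentile 43.1; -0.039 with TMM and -0.070 with median-of-ratios scaling). S phase had 1 of 42 lower, Rrm2 at 0.734, and 41 between (0.043, percentile 94.7; -0.0077 and -0.039 with the same scalings). Splicing genes had 1 of 42 lower and 41 between (0.017, percentile 93.2; -0.033 and -0.064). Ribosomal proteins had 1 of 81 higher and 80 between (0.073, percentile 100; -0.0085 with median-of-ratios scaling). The 3 sex-linked genes were between.

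Beside the smaller myeloid classes, all 8 granulocyte-monocyte progenitor markers were lower (-0.90, percentile 0; Mpo at 0.777, Igsf6 at 0.351), as were all 5 neutrophil (-2.88, percentile 0) and all 5 monocyte markers (-1.21, percentile 0). Dendritic markers had 4 of 6 lower, 1 higher and 1 between (-0.85, percentile 0), with the MHC class II genes Cd74 at 0.359 and H2-Aa at 0.435. Mast cell/basophil markers had 3 of 4 lower and 1 higher (-0.94, percentile 0), with Cpa3 at 0.529, and lymphoid-primed markers 1 of 3 lower and 2 between (-0.16, percentile 5.34). Megakaryocyte markers had 3 of 5 higher and 2 between (0.95, percentile 100), with Itga2b at 2.07 and Gp9 at 1.96. Erythroid markers had 2 of 4 higher, 1 lower and 1 between (0.31, percentile 99.7, but -0.050 as a mean within clusters). Clusters 1, 5, 6, 7 and 8 held 95.5% of the SON cells and 82.5% of the others. Within them the ISG medians were 0.93, 0.57, 0.87, 0.78 and 1.44. For the granulocyte-monocyte progenitor markers, each gene's log2 ratio was averaged over these clusters, and the median of the averages was -0.014. The same median of averages was 0.21 for HSC quiescence genes, 0.25 for HSC/MPP markers and 0.23 for megakaryocyte markers, closer to 0 than over all cells.

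In cKO cells with SON, neutrophil granule genes were nearly absent, most monocyte markers were lower, and ISGs and Ccl5 were lower than in cKO cells with the empty vector. Over all cells both were still above WT, but within HSC/MPP-like cells, which lie mostly in separate clusters by genotype, Ccl5 was closer to the WT level. Camp had 1 UMI with SON, a ratio of 0.000591 (1.49e-05 to 0.00329), and the neutrophil granule gene Ngp had 9, a ratio of 0.00197 (0.000901 to 0.00375). Mpo, the peroxidase of granulocyte progenitors, was at 0.0855. Ccl5 was at 465 against 1031 CPM, a ratio of 0.451 (0.445 to 0.457), and Ifit3 was at 0.405. Hlf, a transcription factor of HSC, was higher at 1.83 (1.69 to 1.98).

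At least 1.5-fold higher with SON were 37 genes and lower were 186, 16.6% higher (TMM 30 and 202, median-of-ratios 30 and 201, without mitochondrial and ribosomal protein genes 52 and 168). The highest were led by genes that share reads with paralogs or pseudogenes and are uncertain, Phpt1 at 2.33, Rnaset2a at 2.22, Rnaset2b at 1.92, Tuba1c at 1.84, Mthfsl at 1.78, Wdr82 at 1.75, Hbb-bt at 1.72 and Wdr89 at 1.71. Rbp1, a retinol-binding protein, was at 2.01, Hypk at 1.66 and Trim47 at 1.65. Below Camp and Ngp came Chil3 at 0.0227, S100a9 at 0.0233, S100a8 at 0.0407, Wfdc21 at 0.0615, Lcn2 at 0.0623, Mcemp1 at 0.0703 and Slpi at 0.0776. The monocyte gene Ly6c2 was at 0.0905, the lipase gene Lipg at 0.0919, Ctsg at 0.0925 and the monocyte chemokine receptor gene Ccr2 at 0.126.

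Inside the cKO-dominated clusters the counts were 20 and 82, of which 17 and 56 are among the 37 and 186. List medians are given over all cells and, after it, inside these clusters. ISGs had 26 of 39 lower and 13 between (-0.41, percentile 0; -0.76 inside), with Isg15 at 0.472 and Irf7 at 0.546. Double-stranded RNA sensing had 5 of 11 lower and 6 between (-0.29, percentile 0.01; -0.54), with Zbp1 at 0.512. Histone transcripts had 19 of 35 lower, 2 higher and 14 between (-0.35, percentile 0; -0.37), with Hist1h4h at 0.490. p53 targets had 5 of 19 lower and 14 between (-0.21, percentile 0; -0.35), with Ccng1 at 0.595 and Phlda3 at 0.671. Cholesterol synthesis had 11 of 22 lower and 11 between (-0.31, percentile 0; -0.15), with Fdps at 0.497 and Mvd at 0.543. MHC class I had 1 of 16 higher, H2-Q7 at 1.37, and 15 between (0.025, percentile 86.1; -0.0073 with TMM and -0.0055 with median-of-ratios scaling; -0.14 inside). Inflammatory genes had 2 of 15 higher, 2 lower and 11 between (0.11, percentile 96.8; -0.12), with Ccl9 at 1.27.

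HSC quiescence genes had 9 of 17 higher and 8 between (0.34, percentile 100; 0.037), with Mecom at 1.62, and HSC/MPP markers 4 of 10 higher and 6 between (0.31, percentile 100; 0.058). MYC targets had 9 of 39 lower and 30 between (-0.19, percentile 0.02; 0.0011), with Pa2g4 at 0.675. The stress response had 8 of 26 lower, 1 higher and 17 between (-0.16, percentile 0.18; 0.043), with Hsp90b1 at 0.586 and Trib3 at 1.44. Glycolysis had 3 of 17 lower, 1 higher and 13 between (-0.087, percentile 9.19; 0.049), with Eno1 at 0.469. S phase had 5 of 42 lower and 37 between (-0.11, percentile 1.16; -0.024), and G2M 1 of 52 higher and 51 between (0.038, percentile 99.6; 0.049). Splicing had 1 of 42 lower and 41 between (-0.10, percentile 12.3; -0.029), and immediate-early genes 2 of 12 lower and 10 between (-0.054, percentile 24.8; -0.027). Ribosomal proteins had 1 of 81 lower and 80 between (0.082, percentile 100; 0.052), mitochondrially encoded genes 1 of 13 lower and 12 between (-0.074, percentile 27.4; 0.015), and the respiratory chain 1 of 28 lower and 27 between (-0.080, percentile 24.8; 0.066). The m6A machinery had 1 of 15 higher and 14 between (0.13, percentile 98.6; 0.018), and the 3 sex-linked genes were between (-0.085).

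All 8 granulocyte-monocyte progenitor markers (-2.14, percentile 0; -0.34 inside) and all 5 neutrophil markers (-5.42, percentile 0; -4.29) were lower, as were 4 of 5 monocyte markers, with 1 between (-2.67, percentile 0; -0.038). Lymphoid-primed markers had 2 of 3 lower and 1 between (-0.84, percentile 0.075; 0.25), with Ighm at 0.167. Mast cell/basophil markers had 3 of 4 lower and 1 between (-1.01, percentile 0; -0.21), with Cpa3 at 0.465, and dendritic markers 1 of 6 lower and 5 between (-0.24, percentile 0.99; -0.34). Megakaryocyte markers had 2 of 5 higher and 3 between (0.27, percentile 99.7; 0.0075), with Itga2b at 1.46. Erythroid markers had 2 of 4 higher, 1 lower and 1 between (0.32, percentile 99.9; -0.0039), with Tfrc at 0.366. Granulocyte-monocyte progenitor and monocyte markers were thus closer to 0 inside the cKO-dominated clusters. Neutrophil markers with the empty vector were already at -8.43 there against WT (-1.63 over all cells), so their -4.29 compares traces. Within clusters 0, 2, 3 and 4 Ccl5 was at 0.336, 0.567, 0.247 and 0.312 and the ISG medians were -0.76, -0.54, -0.73 and -0.68.

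**Figure D4:**
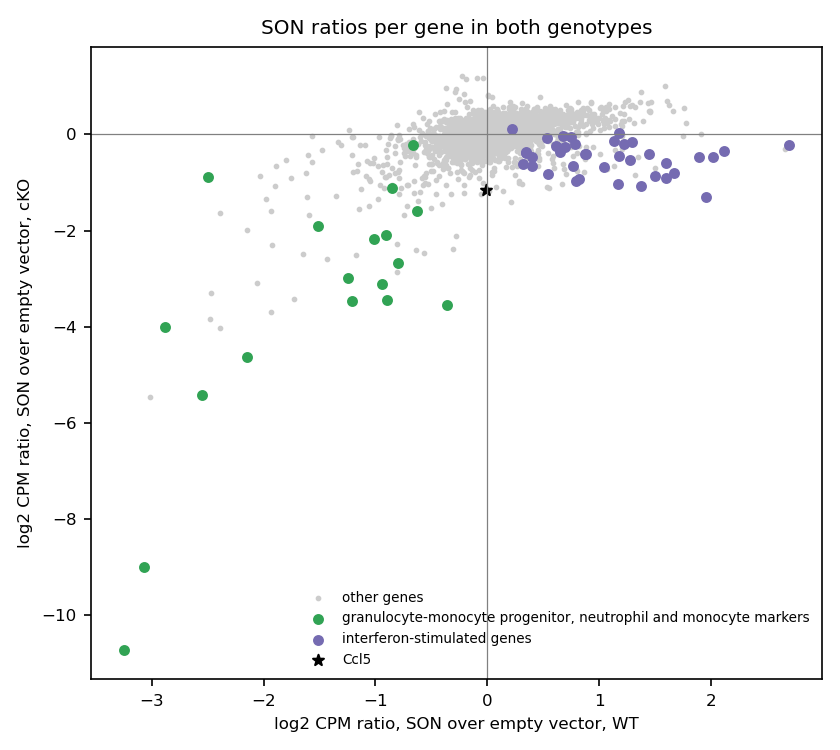
Log2 SON over empty CPM ratio of each gene in WT (horizontal) and in cKO (vertical), with myeloid markers in green, ISGs in purple and Ccl5 as a star. Most myeloid markers lie low on both axes, and ISGs lie right of 0 but mostly below it.

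Against WT with the empty vector, cKO cells with SON had, over all cells, higher stem-cell genes, ISGs and Ccl5, and almost no neutrophil transcripts. Gprc5b was at 38.5 (30.6 to 49.0), Ccl5 at 2.31 (2.27 to 2.36) and Rtp4 at 10.7. Within HSC/MPP-like cells, the only class with enough cells for this comparison, Ccl5 was at 1.06 (1.04 to 1.09). These cells lie in clusters 0 and 3 in cKO, but in WT 765 lie in cluster 1 and 15 in cluster 3. The 15 cells raise the WT level of Ccl5, so the ratio would be higher against cluster 1 alone. Camp was at 0.000178 (4.52e-06 to 0.000994) and Ngp at 0.000639 (0.000292 to 0.00121). Son was at 1.14.

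At least 1.5-fold higher were 1217 genes and lower were 1087, 52.8% higher (TMM 1046 and 1370, 43.3%; median-of-ratios 1004 and 1480, 40.4%; without mitochondrial and ribosomal protein genes 1477 and 773, 65.6%). The median log2 ratio of all genes was -0.047 with total UMIs, -0.15 with median-of-ratios scaling and 0.057 without mitochondrial and ribosomal protein genes. High genes included Zfp467 at 32.6, Phlda2 at 25.9, Ltb at 18.1, Serpina3f at 16.5, the platelet adhesion gene Selp at 15.7, Apoe at 14.96, the transporter gene Slc16a9 at 14.8 and Pdzk1ip1 at 13.8. Trim47 was at 11.6, Gng11 at 11.4 and Eva1b at 10.8. Low genes included Chil3 at 0.00507, S100a9 at 0.00765, S100a8 at 0.0146, Mcemp1 at 0.0154, Lcn2 at 0.0177, Wfdc21 at 0.0207, F10 at 0.0224, Cybb at 0.0245, Ly6c2 at 0.0277 and Lpl at 0.0292.

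HSC quiescence genes had 15 of 17 higher and 2 between (1.16, percentile 100), with Mecom at 7.89. HSC/MPP markers had 6 of 10 higher and 4 between (1.01, percentile 100), with Ly6a at 6.99. ISGs had 31 of 39 higher, 1 lower and 7 between (1.01, percentile 100), with Ifit1 at 5.99. MHC class I had 11 of 16 higher, 2 lower and 3 between (0.75, percentile 100), inflammatory genes 9 of 15 higher, 1 lower and 5 between (0.48, percentile 99.7; Ccl9 at 3.73), and double-stranded RNA sensing 6 of 11 higher and 5 between (0.36, percentile 95.03). The m6A machinery had 8 of 15 higher, 3 lower and 4 between (0.37, percentile 98.8), with Rbm15 at 2.44 and Ythdf2 at 2.13. Ribosomal proteins had 19 of 81 higher and 62 between (0.17, percentile 100), and histone transcripts 11 of 35 higher, 6 lower and 18 between (0.091, percentile 93.3; -0.013 with median-of-ratios scaling). Cholesterol synthesis had 20 of 22 lower and 2 between (-1.11, percentile 0), with Fdps at 0.237 and Hmgcs1 at 0.257. Glycolysis had 13 of 17 lower, 2 higher and 2 between (-0.95, percentile 0), with Eno1 at 0.301 and Ldha at 0.389. The stress response had 18 of 26 lower, 1 higher and 7 between (-0.62, percentile 0), with Hsp90b1 at 0.320 and Asns at 0.436. MYC targets had 25 of 39 lower, 1 higher and 13 between (-0.58, percentile 0), and S phase 25 of 42 lower, 4 higher and 13 between (-0.41, percentile 0.11), with Nasp at 0.422. Splicing had 23 of 42 lower, 2 higher and 17 between (-0.35, percentile 2.57), the respiratory chain 14 of 28 lower, 3 higher and 11 between (-0.33, percentile 3.79), and G2M 16 of 52 lower, 8 higher and 28 between (-0.14, percentile 57.0). Immediate-early genes had 4 of 12 higher, 3 lower and 5 between (-0.19, percentile 23.9). p53 targets had 7 of 19 higher, 3 lower and 9 between (-0.085, percentile 30.3; 0.019 without mitochondrial and ribosomal protein genes in the total), and all 13 mitochondrially encoded genes were between (-0.052, percentile 59.7; 0.052 by that total). Of the 3 sex-linked genes, 1 was lower and 2 between.

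All 8 granulocyte-monocyte progenitor markers (-3.29, percentile 0; Mpo at 0.0387), all 5 neutrophil markers (-7.03, percentile 0) and all 3 lymphoid-primed markers (-2.15, percentile 0.04; Flt3 at 0.0576) were lower. Monocyte markers had 4 of 5 lower and 1 higher (-4.17, percentile 0), and mast cell/basophil markers 3 of 4 lower and 1 higher (-2.83, percentile 0). Dendritic markers had 2 of 6 lower, 1 higher and 3 between (-0.19, percentile 35.9). Erythroid markers had 3 of 4 higher and 1 lower (1.45, percentile 100, but -0.69 without a minimum CPM), with Tfrc at 0.179, and megakaryocyte markers 3 of 5 higher and 2 between (0.39, percentile 95.6), with Itga2b at 2.99.

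Dividing the SON ratio in cKO by that in WT, ISGs and Ccl5 stood out as lower in cKO. Ifit3 was at 0.105 (0.0868 to 0.126), Iigp1 at 0.128, Ifi44 at 0.132 and Ccl5 at 0.456 (0.444 to 0.468). Over all cells granule genes were lower too, though for Camp and Ctsg this depended on the cells compared. Camp was at 0.00559, without an interval since 1 UMI was left with SON in cKO, Ngp at 0.0166 (0.00712 to 0.0282), Mpo at 0.110, S100a9 at 0.137 and Ctsg at 0.172. With the cKO cells restricted to the cKO-dominated clusters, Camp turned to log2 0.38 and Ctsg to 0.60, and as a mean within classes or clusters Camp was at 0.89 or 0.22. The lysozyme gene Lyz2 was higher at 3.08 (2.95 to 3.22), as were the urokinase receptor gene Plaur at 2.92 (2.52 to 3.37) and Ifi30, a thiol reductase gene of antigen processing, at 2.51. Phpt1 at 2.72, Rnaset2a at 2.53, Lilrb4a at 2.41, Lilr4b at 2.36 and Rnaset2b at 2.33 share reads with paralogs and are uncertain. Son was at 0.959 (0.939 to 0.980), Mettl3 at 0.924 (0.791 to 1.08) and Myc at 0.953 (0.903 to 1.01). These values are over all cells, while inside the cKO-dominated clusters Mettl3 and Myc had a higher CPM with SON than with the empty vector.

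At least 2-fold higher were 21 genes and lower were 110 (TMM 24 and 106, median-of-ratios 25 and 101, without mitochondrial and ribosomal protein genes 24 and 109). List medians were -1.42 for ISGs (38 of 39 lower), -1.42 for double-stranded RNA sensing (9 of 11), -0.61 for histone transcripts (28 of 35 lower, 1 higher), -0.40 for MHC class I (12 of 16) and -0.32 for HSC quiescence genes (8 of 17), all at percentile 0. Glycolysis was at -0.31 (7 of 17 lower) and mitochondrially encoded genes at 0.25 (5 of 13 higher, 2 lower). For glycolysis this held over all cells only. Its median was -0.028 with the cKO cells restricted to the cKO-dominated clusters and -0.051 with means of within-cluster ratios. The remaining lists were closer to 0, at -0.17 for S phase, 0.14 for the m6A machinery, -0.13 for MYC targets, splicing and the stress response, 0.11 for inflammatory genes, -0.10 for cholesterol synthesis, 0.081 for G2M, 0.048 for p53 targets and 0.0038 for ribosomal proteins. Immediate-early genes were at -0.020 and the respiratory chain at -0.026, and both turned direction with median-of-ratios scaling (0.031 and 0.025). Markers were at -2.87 for neutrophils, -1.75 for monocytes, -1.18 for granulocyte-monocyte progenitors, -0.69 for lymphoid-primed cells, -0.50 for megakaryocytes, -0.38 for HSC/MPP, -0.15 for erythroid and -0.13 for mast cells, and 0.71 for dendritic cells. With the cKO cells restricted to the cKO-dominated clusters and all WT cells kept, the ISG median was -1.68, but granulocyte-monocyte progenitor markers were at 0.78 and monocyte markers at 0.76. These last values set cKO clusters outside those classes against WT medians over all cells of -0.90 and -1.21. They are therefore no ratio of ratios within the same clusters.

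SON over empty was at least 1.5-fold lower in both genotypes for 82 genes, such as Camp, S100a8 and Lyz2, where 3.50 would share by independence, and higher in both for 17 (1.26). For 25 genes, such as Ifit3, Isg15 and Hist1h4h, it was higher in WT and lower in cKO (6.35), and for 0 the other way (0.697). Over all genes the 2 log2 ratios had r 0.51, but r was 0.049 when the cKO cells were restricted to the cKO-dominated clusters. Genes are not independent replicates of each other.

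Of the 842 genes higher in cKO with the empty vector, 28 (3.33%) were at least 1.5-fold lower with SON in cKO, where independence gives 20.5, and of the 501 lower genes 3 (0.599%) were higher with SON, where independence gives 2.42. These shares depended on the genes compared, at 12.4% and 17.0% without a minimum CPM. As means within classes they were 20.3% and 5.26%, and within clusters 25.7% and 2.17%, but there the 2 ratios come from different cells. Within clusters, cKO over WT rests on clusters 5, 6 and 7 and SON over empty on clusters 0, 2, 3 and 4, with no cell in common. Within classes, the first rests on 4 classes and the second on the HSC/MPP-like class alone. Neither pair of shares measures return toward WT in a single set of cells. Over all cells, more genes moved further from WT than back among the lower ones, with 116 of 501 also lower with SON (12.2 by independence), next to 18 of 842 also higher (4.07). The 28 include Ccl5, ISGs such as Ifit1, Isg15 and Irf7, and histone transcripts, the 3 include Hlf, and the 116 include granule and monocyte genes such as Camp, Mpo and Ccr2. Both ratios share the cKO empty-vector library, which by itself makes their counting errors opposed. In simulations without a SON effect 0 and 0 genes returned, with covariance -0.0011, against an observed covariance of 0.089 and r 0.46. At this depth counting noise puts 0 unchanged genes past 1.5-fold, so the simulated 0 and 0 were fixed in advance. They speak to counting noise only. With the cells of that library split at random into 2 parts, the shares were 3.11% and 0.586%, covariance 0.088. Counting errors of the shared library therefore account for little of these shares. A difference in its preparation would still enter both ratios and was not tested. In the cKO-dominated clusters 54 of 1305 (4.14%) and 5 of 1171 (0.427%) returned, r 0.046, covariance 0.0076, and only 16 of the 1171 were also lower and 1 of the 1305 also higher with SON.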

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

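The tests of this part were written before their values were seen, though the means over clusters that the first of them uses were added after the cells had been clustered.

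Several interferon genes had opposite directions with SON in the 2 genotypes, and the difference of the log2 ratios (cKO minus WT) was far below 0. It was -3.25 for Ifit3 (1.95 in WT, -1.30 in cKO), -2.48 for Ifit1 (1.67, -0.81), -2.46 for Isg15 (1.37, -1.08) and -2.37 for the regulator Irf7 (1.496, -0.87). For genes of RNA sensing it was -2.19 for Oas3 (1.59, -0.60) and -1.75 for Zbp1 (0.79, -0.97). Plainly, these antiviral transcripts were higher with SON where their starting level was low (WT) and lower where it was high (cKO). Replication-dependent histone genes showed the same, at -1.64 for Hist1h2ae (0.86, -0.78) and -1.70 for Hist1h4h (0.67, -1.03), although tags of these genes can be shared within the family. At the level of lists the difference was -1.29 for ISGs (0.88 in WT, -0.41 in cKO), -1.06 for double-stranded RNA sensing (0.76, -0.29) and -0.65 for histone transcripts (0.30, -0.35). None of these differences was tested, since each ratio rests on 1 library against 1 library.

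The higher ISGs in WT with SON could come from the larger share of HSC/MPP-like cells, but the mean within-cluster median over 5 clusters was 0.92 (0.57 to 1.44 across them), so that explanation did not hold. Scaling could not be judged by TMM and median-of-ratios factors, which shift all genes alike, here by log2 -0.050 and -0.082. Shifts of that size could hardly move the list median, and the lowest median under these factors and thinning was 0.80. With cells thinned the median was no lower than 0.80, so the larger weight of deep cells in the sums did not account for it. Thinning leaves the expected make-up of each cell unchanged, so other effects of depth per cell could not be judged by it. An effect of SON itself remains a hypothesis, and so does a difference between the 2 infections, such as the amount of virus, which lentivirus-exposed cells may read as foreign RNA or DNA. A repeat with at least 3 independent infections per vector and a matched titre would separate them.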

How the results depend on the processing

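Of the settings below, 4 were chosen after the data had been seen: the cKO libraries restricted to the cKO-dominated clusters, means of within-cluster ratios, free RNA taken from barcodes with 100 to 400 UMIs, and clustering without interferon, MHC class I and double-stranded RNA sensing genes. All others were fixed before. No paired analysis was possible because the labels tie no library to another and each group has 1 library. The comparisons are named cKO/WT (empty vector), SON/empty in WT, SON/empty in cKO, cKO SON/WT, and the ratio of ratios (SON/empty in cKO over that in WT).

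Counts of genes past 1.5-fold depend on the minimum level. At a mean CPM of 5, SON/empty in WT had 437 higher and 222 lower, SON/empty in cKO 75 higher, and the ratio of ratios 35 higher, and its monocyte marker median became 0.33 instead of -1.75. At 50 CPM there were 212 higher and 179 lower for cKO/WT, 54 and 44 for SON/empty in WT, 7 and 72 for SON/empty in cKO, 273 and 467 for cKO SON/WT, and 6 and 33 for the ratio of ratios. Without a minimum there were 4622 and 2492, 2936 and 1790, 1785 and 2076, 5324 and 3355, and 856 and 1618 in the same order. Erythroid markers then had medians of -0.39 (cKO/WT) and -0.69 (cKO SON/WT) instead of 0.89 and 1.45, and 12.4% and 17.0% of genes returned toward WT instead of 3.33% and 0.599%. Past 2-fold there were 324 and 98 for cKO/WT, 84 and 60 for SON/empty in WT, 5 and 84 for SON/empty in cKO, and 539 and 312 for cKO SON/WT.

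Scaling turned the direction of the small Son ratios. Their log2 values for SON/empty in WT and in cKO were -0.018 and -0.060 with TMM, -0.049 and -0.058 with median-of-ratios, and 0.062 and 0.011 without mitochondrial and ribosomal protein genes in the total, against 0.033 and -0.028. By construction such factors shift all genes alike, so the direction of Son over all cells depends on the scaling. Inside the cKO-dominated clusters Son was lower with SON, at -0.13, which is further from 0 than these shifts.

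With a cell threshold of 20%, SON/empty in cKO had 61 genes higher instead of 37. With each cell weighted equally it had 19, cKO/WT had 924 lower instead of 501, and Son in WT was at 0.056. With cells thinned, the same counts were 22 and 907, and Mettl3 for cKO/WT was at -1.49 instead of -1.30. Both settings weigh shallow cells more, and the cKO-dominated clusters are shallower, but the cause was not tested.

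Means of within-class ratios, over 4 classes for cKO/WT and SON/empty in WT and the HSC/MPP-like class alone for the others, left fewer genes: 153 higher and 95 lower for cKO/WT, 70 and 28 for SON/empty in WT, 22 higher for SON/empty in cKO, and 9 higher for the ratio of ratios. They covered 58.1% of the cKO cells with the empty vector and 52.6% of those with SON. Mettl3 was at -0.83 for cKO/WT, and Son at -0.00082 in WT and -0.13 in cKO. Of genes higher in cKO 20.3% returned with SON, and of genes lower 5.26%. Directions turned for Ccl5 (-0.28), Igsf6 (0.67), Lyz2 (0.012), Zmat3 (-0.0037) and the inflammatory list (-0.055) in cKO/WT. In SON/empty in WT they turned for Cebpb (0.12), Cpa3 (0.12), Gp9 (-0.36) and Igsf6 (0.11), and for erythroid (-0.051), granulocyte-monocyte progenitor (0.075), mast cell (0.023) and megakaryocyte markers (-0.097). Elsewhere they turned for Cybb in cKO SON/WT (0.87), megakaryocyte markers in SON/empty in cKO (-0.030), and Camp (0.89), Lilr4b (-0.43), Lilrb4a (-0.36) and megakaryocyte markers (0.040) in the ratio of ratios. Most of these genes mark a class, so their all-cell ratios follow class shares by construction.

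Means of within-cluster ratios left 70 higher and 92 lower for cKO/WT (clusters 5, 6 and 7), 95 and 23 for SON/empty in WT, 17 and 94 for SON/empty in cKO, and 12 higher for the ratio of ratios. The shares counted as returning were 25.7% and 2.17%. SON/empty in cKO rests on clusters 0, 2, 3 and 4 here, so the 2 ratios share no cell and return cannot be read from these shares. Mettl3 was at -0.54 for cKO/WT and Son at -0.13 in cKO. In cKO/WT directions turned for Ccl5 (-0.97), Cpa3 (0.014), Fen1 (-0.035), H1f0 (-0.21), Igsf6 (0.15), Phlda3 (-0.23), Rbm15 (-0.067), Tfrc (0.22) and Zmat3 (-0.26), and for the lists of HSC quiescence (-0.041), MYC targets (0.019), inflammatory genes (-0.14), stress response (0.0059) and respiratory chain (0.032). The smaller medians of p53 targets (-0.21 instead of 0.19) and the m6A machinery (-0.067 instead of 0.16) crossed 0 too. These clusters are the ones the cKO library shares with WT, with a higher Mettl3 level, and leave out the cKO-dominated ones. In SON/empty in WT directions turned for Cebpb (0.045), Igsf6 (0.014) and erythroid markers (-0.050), in SON/empty in cKO for lymphoid-primed markers (0.23), and in the ratio of ratios for Camp (0.22), Lilr4b (-0.23), Lilrb4a (-0.070) and lymphoid-primed markers (0.31). The cause was not tested for these.

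With the cKO libraries restricted to the cKO-dominated clusters, cKO/WT had 1305 genes higher and 1171 lower, SON/empty in cKO 20 and 82, and the ratio of ratios 61 higher. Mettl3 was at -1.69 for cKO/WT and Son at -0.13 for SON/empty in cKO. In SON/empty in cKO directions turned for Ccr2 (0.041), erythroid (-0.0039) and lymphoid-primed markers (0.25). In the ratio of ratios they turned for Camp (0.38), Ctsg (0.60), and granulocyte-monocyte progenitor (0.78), lymphoid-primed (0.17) and monocyte markers (0.76). Neutrophil markers in SON/empty in cKO were at -4.29 there, a ratio of traces, since with the empty vector they were at -8.43 in cKO/WT in this setting (-1.63 over all cells).

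Class shares depended on the clustering, given here in the order WT empty, WT SON, cKO empty, cKO SON. HSC/MPP-like cells were 16.8%, 45.7%, 48.5% and 56.5% with 4000 variable genes, 8.22%, 31.6%, 36.4% and 43.3% at resolution 1.0, and 14.1%, 40.3%, 49.5% and 63.9% without interferon genes. With doublets kept they were 17.0% in WT empty, 38.3% in cKO empty and 44.0% in cKO SON, and with mitochondrial UMIs limited to 5% they were 20.3% and 54.1% in the WT libraries. Granulocyte-monocyte progenitor-like cells (WT empty, WT SON, cKO empty) were 27.6%, 15.9% and 10.2% with 4000 variable genes, 27.4%, 12.2% and 9.04% at resolution 0.3, 12.1%, 5.50% and 5.74% at resolution 1.0, and 32.6%, 15.4% and 11.3% at the 5% mitochondrial limit. In the WT libraries they were 27.4% and 17.0% without interferon genes and 25.2% and 15.7% with doublets kept. Other classes moved as well. Mature neutrophil-like cells were 10.7% and 4.56% of the WT libraries with 4000 variable genes, against 4.65% and 0.507% as reported and 3.11% and 0.135% at the 5% mitochondrial limit. Monocyte-like cells were 8.24% of WT empty as reported, 15.5% at resolution 1.0, 14.0% with doublets kept and 13.2% without interferon genes. Lymphoid-primed-like cells were 2.99% of cKO empty as reported, 1.62% with 4000 variable genes, 1.79% without interferon genes, 1.56% with doublets kept, 0.965% at the 5% mitochondrial limit and under 1% at resolution 1.0. At that resolution megakaryocyte-like cells were 9.42%, 14.9%, 1.22% and 0.744%, next to an erythroid-like class of 5.72%, 7.39%, 2.11% and 0.434%. At resolution 0.3 no cluster passed the naming rule as HSC/MPP-like. In the other settings these cells were the smallest share in WT empty, while whether WT SON lay above or below cKO empty depended on the clustering.

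Cells in S or G2M phase were 89.2% of WT SON, 78.5% of cKO empty and 76.4% of cKO SON with doublets kept. At the 5% mitochondrial limit they were 90.1%, 85.7%, 73.1% and 71.8% over the 4 libraries. Without thinning cKO empty had 74.7%, and thinned to 8000 UMIs WT SON had 90.5%, cKO empty 86.6% and cKO SON 80.4%, with shallower cells left out.

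Over all settings, 1573 of 2612 values of list medians stayed within their counting interval, 1016 were outside it in the same direction or near 0, and 23 turned direction. For named genes these were 2392, 1165 and 29 of 3586. A turned direction was counted only for medians at least 0.2 from 0 over all cells and for genes past 1.5-fold (2-fold for the ratio of ratios), and smaller values that crossed 0 stand among the others. Of 187 named ratios past 1.5-fold, 186 stayed so with TMM, 184 with cells thinned, 173 in the cKO-dominated clusters and 141 as means within classes, and of the 143 with a mean within clusters 89 did. Subtracting free RNA left all 187 past 1.5-fold with either set of barcodes, but it took off at most 272 UMIs per cell and could move little. Cells of the cKO libraries were shallower (median 9848 and 11246 against 18938 and 15168 UMIs), so rare transcripts rest on fewer UMIs per cell there, while the summed counts of 62367091 to 79693120 UMIs limit ratios little at 10 CPM.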

Other observations

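In this part, the first and the last test of the myeloid pattern below were written after its result had been seen, and all others before.

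Ccl5 in WT shows how a mixed library can hide a difference between cells. Over all WT cells its SON ratio was 0.988, but within HSC/MPP-like cells it was 0.552 (0.652 in cluster 1 alone), within megakaryocyte-like cells 0.400, and within the other 2 classes with at least 100 cells in both libraries it was 0.626 (lymphoid-primed) and 0.782 (granulocyte-monocyte progenitor). HSC/MPP-like cells carry the most Ccl5 of these classes and were a larger share with SON, which offsets the lower level within them. Without the few WT cells in cKO-dominated clusters, Ccl5 was at 180 CPM with the empty vector and 196 with SON. In the unnamed cluster 8 there was no difference, at 0.983 (0.851 to 1.14). Ccl5 was therefore lower with SON within these named classes in WT and within HSC/MPP-like cells in cKO, unlike the ISGs, which were higher in WT and lower in cKO.

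Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, was lower with SON over all cells in both genotypes, at ratios of 0.775 in WT and 0.688 in cKO. In WT it was not lower within HSC/MPP-like cells, at 1.05 (0.989 to 1.11), or within cluster 8, at 1.01, but was at 0.587 in megakaryocyte-like, 0.546 in granulocyte-monocyte progenitor-like and 0.839 in lymphoid-primed-like cells. Within the cKO-dominated clusters 0, 2, 3 and 4 it was at 0.679, 0.750, 0.449 and 0.590, next to p53 list medians of -0.21, -0.20, -0.65 and -0.46. Histone transcripts were lower in the same 4 clusters, at -0.44, -0.44, -0.58 and -0.25. Against WT with the empty vector, Cdkn1a was at 1.14 in cKO with the empty vector and 0.787 in cKO with SON.

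The first pattern is the lower level of myeloid genes in cKO with SON, near absence only for neutrophil granule genes. A different share of cells outside the cKO-dominated clusters may contribute to it. With those cells left out, and the clusters drawn without these genes and the markers, the median log2 ratio of the 186 lower genes was -0.22 instead of -0.91, and 57 stayed lower. These 186 are all genes past 1.5-fold lower in this comparison, Ccl5 and ISGs such as Isg15 among them, not a myeloid list. They were chosen by their all-cell ratio, and the cells left out include the myeloid classes. A move toward 0 was therefore likely from the start and does not decide the matter. Neutrophil markers were at -4.29 inside the cKO-dominated clusters (-5.42 over all cells), but this compares traces, since with the empty vector they were at -8.43 against WT there and at -1.63 over all cells. WT droplets read under the same barcodes do not account for those cells, as 1 of 1206 (0.0829%, 0.0021 to 0.461) shared one with a kept WT cell. Nor had they, pooled over clusters, kept Mettl3 at the WT level, at a ratio of 0.601 (0.519 to 0.694), or 0.653 with the WT cells at the same mix of clusters. A mixture of cells that kept and lost Mettl3 may give such a value, and tags outside the deleted part do not measure the deletion. Reading Mettl3 deletion per cell from genomic DNA would decide what those cells are.

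The other pattern weighed here is the lower Ccl5 in cKO with SON. A different share of cells outside the cKO-dominated clusters could not explain it, since Ccl5 was at 0.327 (0.323 to 0.332) within them. Neither could a few cells with very high Ccl5, with a ratio of 0.383 (0.377 to 0.389) without the top 1% of cells, which held 14.6% and 27.6% of its UMIs with the empty vector and SON. Free RNA could not be judged this way. Ccl5 stood at 1393 and 507 CPM in it in these libraries, and subtracting it left the ratio at 0.454. Only 272 and 255 UMIs per cell were taken off, against medians of 9848 and 11246 UMIs per cell, so the ratio could hardly have moved. SON acting on Ccl5 or on the interferon signal remains a hypothesis that replicate infections and a protein measurement of CCL5 in the medium could test.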
